A study of Mus musculus with 8 samples.

How the data were processed

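The samples were mesonephric tubules of mouse embryos of a C57BL/6 strain, cut from toluidine blue stained frozen sections, with total RNA hybridised to 1-colour Agilent arrays. Per the file headers, the deposited scanner files came from Agilent Feature Extraction 10.7.3.1 and hold spot intensities on a linear scale: a processed intensity, already corrected for background and for trends across the slide by that software, and the median intensities of each spot and of its local background. Nothing in those files was normalized between arrays, and replicates were not pooled. A table of the series, deposited by the authors, holds log2 values per probe; the submitters' processing notes name limma, and its background correction is not given in the sources used here. Its columns all had a median near 9.26 and the same extremes. Set against each array's scanner values they correlated at 0.99995 or higher with the log2 of normexp-corrected, quantile-normalized intensities, which settles scale and direction; no gene was centred.

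Each array held 62976 spots, of which 59305 were not controls, and 55681 distinct probes. The files name no genes, so accessions were matched without versions to a RefSeq table of assembly GRCm38.p6. It gave a symbol for 26056 probes and none for 29625. That table was used only for names, for chromosomes and for which genes neighbour each other. The log2 of the processed intensity was taken minus the 75th percentile of each array over spots that were not controls. Spots marked as outliers by the software were left out and spots of 1 probe were averaged. Probes were kept if well above background on at least 3 of the 8 arrays, whatever the group (50046 probes). Where a gene had several probes, the probe with the highest mean over all arrays stood for it, which left 33619 genes and unnamed features, 18164 of them with a symbol.

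Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 5 wild-type against 3 labelled p21-null arrays, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A second count took genes with an unadjusted p under 0.01 and at least a 2-fold change. Differences are log2 means of labelled p21-null arrays minus wild-type arrays, and folds are their antilogs. Where a probe was not well above background on any array of a group, the fold is a bound: the mean of the brighter group against the mean, in the dimmer group, of the higher of its own value and the lowest signal among probes well above background on that array. The 30 gene lists were fixed before the data were examined, and each had at least 5 measured members. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Members were adjusted over all genes and over the list alone. List means per array were compared by two-sided exact permutation tests of all 56 splits, whose smallest possible p is 0.0179.

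The genes open to naming were fixed by rule: Cdkn1a and the list of its relatives, the 15 named genes with the smallest p in each direction where fewer passed the adjusted threshold, the 4 members of smallest p in each list, and all sex-linked genes of the list; some of these genes are not reported here. Slides were read from the file names; slide 1 held wild-type replicates 1, 2 and 3 and labelled p21-null replicate 1, slide 2 held wild-type replicate 4 and labelled p21-null replicate 2, and slide 3 held wild-type replicate 5 and labelled p21-null replicate 3. All arrays were scanned on 1 day. The local background averaged 40.2 to 47.0 on slide 1 and 94.0 to 138 on slides 2 and 3.

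Alternatives were quantile or median scaling, normexp background correction with an offset of 50 on the median spot and background intensities (the planned mean intensity is not a column of these files), no filter or a stricter filter on dim probes, slide as a fixed or random block, the replicate number as a block, other rules from probe to gene, trend and robust moderation, array weights, the deposited log2 table, and leaving out each array in turn. The liver and erythroid list means were added as covariates after the data were seen. On simulated data for this comparison, with the real residual spread of 33619 genes, limma recovered at an adjusted p under 0.05 0% of 50 genes changed by 1 on the log2 scale, 42% of 50 changed by 2, 56% of 50 changed by 3 and 72% of 50 changed by 4, with 6 false calls. On simulated independent genes camera called 0 of 30 lists with no shift, but these genes lack the correlation of the real ones: over the other splits of the real arrays it called a median of 10.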

Results

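Gene expression was measured by array in mesonephric tubules cut by microdissection from stained frozen sections of mouse embryos. The mesonephros is a transient embryonic kidney that regresses before birth, and the design sets tubules of wild-type embryos, described as senescent, against tubules of embryos that lack p21, described as non-senescent. p21, encoded by Cdkn1a, is a cyclin-dependent kinase inhibitor that can arrest the cell cycle. There were 5 wild-type arrays and 3 arrays labelled p21-null, each hybridised with 1 sample in 1 colour (Cy3). The labels give neither the embryonic stage nor whether each sample came from a separate embryo, so p-values measure only the spread between these samples. Between 82.2% and 89.2% of 55681 probes were well above background on an array, and no spot was saturated. The number of arrays limits the precision. The arrays lay on 3 slides, each of which held both groups, and pairs of arrays correlated between 0.866 and 0.952.

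Cdkn1a itself was read by 2 probes, and neither was clearly lower in the arrays labelled p21-null. On probe 1 the log2 signal, relative to the 75th percentile of the array, was 2.49, 2.52, 0.44, 1.85 and 1.11 in wild-type replicates 1 to 5 and 2.11, 0.96 and 1.40 in labelled p21-null replicates 1 to 3. The means were 1.68 ± 0.90 (SD, n = 5) and 1.49 ± 0.58 (SD, n = 3), a difference of −0.19 with a standard error of 0.54 (limma adjusted p = 0.950). A two-sided exact permutation test of the 56 splits of the arrays gave p = 0.768 for that probe. Probe 2 averaged −1.57 ± 0.47 in wild type and −1.81 ± 0.33 in the arrays labelled p21-null, and the exact permutation test gave p = 0.482. With slide as a block the difference on probe 1 was −0.0446, and within slides 1, 2 and 3 it was 0.30, −0.89 and 0.29. Its sign turned to positive without wild-type replicate 1 (0.0114), without wild-type replicate 2 (0.0188) and without labelled p21-null replicate 2 (0.0758), and with the liver (0.40) or erythroid (0.17) marker mean as a covariate. The sources used here do not place either probe relative to the deleted part of the gene, and a probe outside that part checks nothing. The group is therefore called labelled p21-null throughout, and every direction given here rests on that label.

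**Figure D1:**
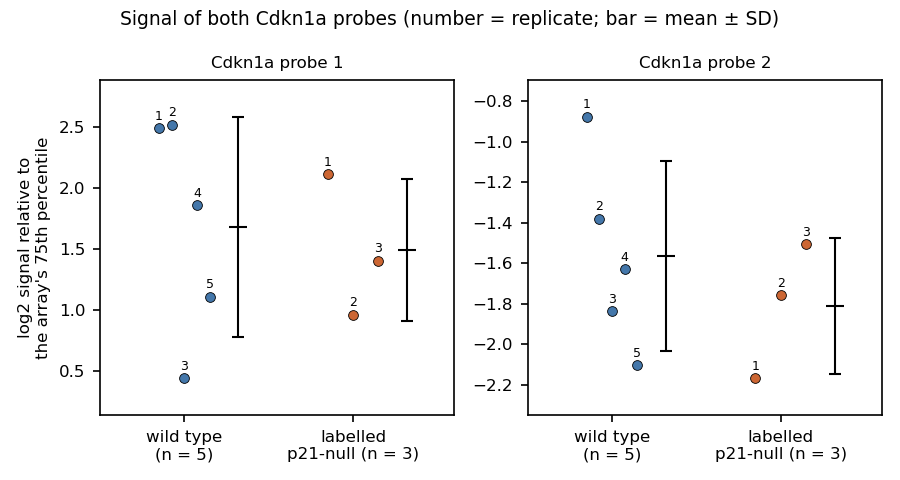
Signal of both Cdkn1a probes on each array, as log2 signal relative to the 75th percentile of the array (vertical axis), in 5 wild-type and 3 labelled p21-null arrays; the number at a point is its replicate and the bar is the group mean ± SD. On probe 1 the labelled p21-null arrays, at 0.96 to 2.11, lie within the wild-type range of 0.44 to 2.52.

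Across the whole array the genes with the smallest p-values were secreted liver proteins and antigen-presentation genes on the higher side, and neuronal or developmental genes on the lower side, in the arrays labelled p21-null. F11, coagulation factor XI, stood at 0.27 ± 0.55 (SD, n = 3) against −3.24 ± 0.67 (SD, n = 5), a log2 difference of 3.51 with a standard error of 0.45, or 11.4-fold. Hp, haptoglobin, was 10.5-fold higher and Plg, plasminogen, 9.16-fold. Pcp4, a calmodulin-binding protein of neurons, was at least 13.2-fold lower, since its probe was not well above background on any array labelled p21-null. None of these genes passed the adjusted threshold of 0.05.

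Among 33619 genes and unnamed features tested with limma, 0 reached an adjusted p under 0.05, and the smallest adjusted p was 0.148. At an unadjusted p under 0.05 there were 3400 (10.1%). At an unadjusted p under 0.01 with at least a 2-fold change there were 992, a count not corrected for multiple tests, of which 704 were higher and 288 lower in the arrays labelled p21-null. That count fell to 416 without labelled p21-null replicate 1 and to 309 (178 higher, 131 lower) without labelled p21-null replicate 3, and it was 2034 with array weights. Array weights put 8 genes or features past the adjusted threshold. These weights were 3.045 for labelled p21-null replicate 3 and 0.52 to 1.38 for the other arrays, so both counts with them lean on that 1 array. Normexp background correction with the 75th percentile put 3 past the threshold, and leaving out wild-type replicate 4 put 1. With the liver and gut marker mean of each array as a covariate the looser count was 131 (55 higher, 76 lower), and with the erythroid marker mean it was 102 (32 higher, 70 lower), so the excess of higher genes turned over. The share at an unadjusted p under 0.05 was then 2.98% and 2.59%. Both marker means were themselves higher in the arrays labelled p21-null, so these smaller counts cannot tell liver or blood RNA from a group effect. Both covariates were chosen after the data were seen.

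The named genes with the smallest p on the higher side fell short of the adjusted threshold as well. Besides F11, Hp and Plg they included the multimerin gene Mmrn1, 53.6-fold higher but above background on only 1 of 5 wild-type arrays, and Mageb16, 71.9-fold higher with 2 of 5 wild-type arrays above background. Upb1, an enzyme of pyrimidine breakdown, was 9.11-fold higher. The class I histocompatibility gene H2-Q7 was 3.83-fold higher and Tap2, which carries peptides to class I molecules, 4.40-fold, with 3 of 5 wild-type arrays above background. Gpnmb was at least 3.83-fold and the carboxylesterase gene Ces1b at least 2.13-fold higher, neither being above background in wild type. Tmie, Spata9, Ppp1r15b and the phosphatase gene Dusp9 completed the list, at log2 differences of 1.88, 1.61, 1.42 and 1.68. Unadjusted p-values of these genes ran from 2.55e-05 for F11 to 0.000531 for Upb1.

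On the lower side, the 15 named genes of smallest p included receptors and transcription factors of developing tissue. The BMP receptor gene Bmpr1b was 6.97-fold lower, the retinol transporter gene Stra6 7.37-fold, Lmo1 7.75-fold and Foxp2 5.56-fold. Ncam1, a neural cell adhesion molecule, was 4.28-fold lower and Nlgn3, a neuroligin, 6.06-fold. Doc2b was at least 3.75-fold lower, the chloride channel gene Clcn1 at least 5.54-fold, Hoxd3os1 at least 3.49-fold and Gpr143, above background on 4 of 5 wild-type arrays, at least 1.38-fold. Dhh, encoding desert hedgehog, was 3.97-fold lower, Spsb4 5.34-fold and Cacng8, above background on 2 of 3 arrays labelled p21-null, 6.06-fold; Slc35f1 differed by −3.81 on the log2 scale. The adjusted p of Doc2b was 0.148 and that of Pcp4 0.187.

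Markers of liver, blood and macrophages were higher together in the arrays labelled p21-null. The mean of 19 measured liver and gut markers was 2.28 ± 0.52 (SD, n = 3) against 0.58 ± 1.18 (SD, n = 5) in wild type, a log2 difference of 1.70. The mean of 23 erythroid markers differed by 1.47 and that of 30 macrophage markers by 1.17. Apoa1, a plasma apolipoprotein, was 11.3-fold higher, Epb42, a membrane protein of red cells, 7.16-fold, and Lyz1, a lysozyme, 6.87-fold.

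The liver and gut list passed camera with its preset correlation (adjusted p = 1.85e-07) and not otherwise (adjusted p = 0.358 with an estimated correlation). Of its members 16 were higher and 3 lower, and 10 passed when adjusted over the list alone against 0 over all genes tested; Apoa1, Fabp1, Ahsg and Fga each had an adjusted p of 0.0291 over the list. The exact permutation test of its mean gave p = 0.0893. The wild-type arrays were far apart, with replicate 5 at 2.02, above labelled p21-null replicate 2 at 1.70, and replicate 2 at −1.24. Among the erythroid markers 18 were higher and 5 lower, 14 passed when adjusted over the list alone and 0 over all genes (camera adjusted p = 1.25e-09; adjusted p = 0.357 with an estimated correlation). The 14 included the transcription factor gene Nfe2, at 5.14-fold, and Epb42. The macrophage list had 25 members higher and 5 lower, with 0 passing by either adjustment (camera adjusted p = 2.43e-08; adjusted p = 0.357 with an estimated correlation). Its mean was 0.42 ± 0.35 (SD, n = 3) against −0.75 ± 0.70 (SD, n = 5), and the exact permutation test gave p = 0.0536. Tyrobp, Coro1a and Laptm5, expressed across white blood cells, were 3.07-fold, 2.97-fold and 4.25-fold higher. With the liver mean as a covariate the erythroid difference was 0.43, and with the erythroid mean the liver and gut difference was −0.30 and the macrophage one 0.70. With slide as a block the differences were 1.57 for liver and gut, 1.44 for erythroid and 1.11 for macrophage markers. Within slides 1, 2 and 3 they were 2.55, 1.24 and 0.44 for liver and gut, 1.82, 1.48 and 0.85 for erythroid, and 1.45, 1.22 and 0.49 for macrophage markers.

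Genes of DNA replication and mitosis were higher in the arrays labelled p21-null. All but 1 of 40 S-phase genes and all 40 G2/M genes had a positive difference. The S-phase mean was 1.92 ± 0.25 (SD, n = 3) against 1.13 ± 0.29 (SD, n = 5), a log2 difference of 0.79, and the G2/M mean was 1.43 ± 0.32 against 0.73 ± 0.34, a difference of 0.70. Cdc6, which loads the replicative helicase, was 3.07-fold higher, and Mki67, the proliferation marker Ki-67, 2.17-fold.

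For both lists each array labelled p21-null lay above every wild-type array. For G2/M this was by a very small margin, labelled p21-null replicate 2 standing at 1.065 and wild-type replicate 5 at 1.059. The exact permutation test gave p = 0.0179 for the S-phase mean, the smallest that 56 splits allow, and p = 0.0357 for the G2/M mean; over the means of all 30 lists both adjusted to 0.268. Camera gave adjusted p-values of 2.22e-13 and 6.40e-11, and both calls were lost on estimating the correlation (adjusted p = 0.357 with an estimated correlation for each). In the S-phase list 4 genes passed when adjusted over the list alone and 0 over all genes: Cdc6, the transcription factor gene E2f2, 3.37-fold higher, Slbp, which binds histone mRNA, 2.45-fold, and the helicase component Cdc45, 2.31-fold. In the G2/M list 0 passed by either adjustment; Dlgap5, Ccna2, encoding cyclin A2, and the kinetochore gene Nuf2 were 2.13-fold, 2.31-fold and 2.43-fold higher. With slide as a block the differences were 0.73 and 0.65. Within slides 1, 2 and 3 they were 0.98, 0.39 and 0.69 for the S-phase list and 1.03, 0.13 and 0.59 for the G2/M list. The liver and erythroid means moved with the same arrays: with the liver mean as a covariate the S-phase difference was 0.57 and the G2/M difference 0.44, and with the erythroid mean they were 0.47 and 0.33.

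**Figure D2:**
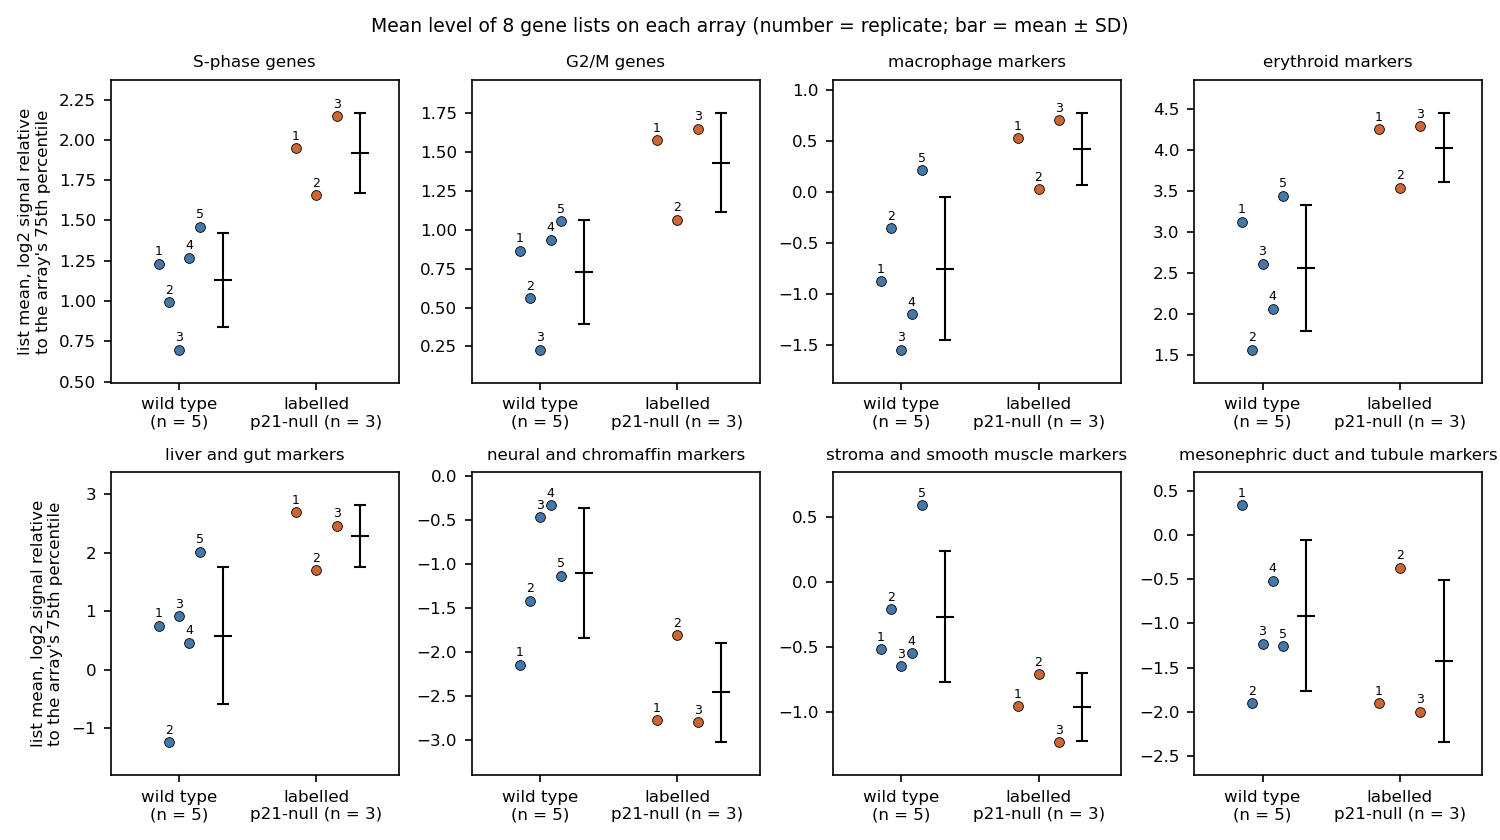
Mean of the measured members of 8 gene lists on each array, as log2 signal relative to the 75th percentile of the array (vertical axes, a separate scale per panel), in 5 wild-type and 3 labelled p21-null arrays; numbers are replicates and bars are group means ± SD. S-phase, G2/M and erythroid means are higher on all 3 arrays labelled p21-null than on any wild-type array, for G2/M by a very small margin (1.065 against 1.059). The mesonephric duct and tubule means overlap.

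The other inhibitors and regulators of the cell cycle did not move as a group. The list of 21 cyclin-dependent kinase inhibitors, G1 cyclins and kinases, and Rb and p53 family members differed by 0.23 (camera adjusted p = 0.236), with 0 members passing over the list alone or over all genes. The difference was 0.13 without wild-type replicate 3, 0.15 without labelled p21-null replicate 2 and 0.36 without labelled p21-null replicate 1. Cdkn2c, encoding p18, was 2.11-fold and Cdkn2d, encoding p19, 2.02-fold higher, with adjusted p-values of 0.206 and 0.292 over the list alone. Ccne1 and Ccne2, the cyclin E genes, were 1.76-fold and 3.32-fold higher, also without passing. Cdkn1b, encoding p27, differed by 0.04 with a standard error of 0.37, a difference that turned negative with quantile scaling (−0.0327), and Cdkn1c, encoding p57, by −0.44 with a standard error of 0.42. Cdkn2b, encoding p15, differed by −1.56 with a standard error of 1.15, with 1 of 3 labelled p21-null arrays above background. Cdkn2a, which encodes p16, was above background on 2 of 5 wild-type and 2 of 3 labelled p21-null arrays.

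Gene groups linked to senescent cells were shifted little, and in both directions. Secreted factors of senescent cells were slightly lower in the arrays labelled p21-null, with a mean difference of −0.32, and so were TGF-β response genes, with −0.33. Both differences were smaller than the wild-type SD of the list mean (0.36 and 0.43). The exact permutation test gave p = 0.304 for each. Lysosomal genes were higher by 0.45, on the same arrays as the macrophage markers, which were higher by 1.17. Plau, the urokinase gene, was at least 2.55-fold lower and Pmepa1, a TGF-β target, 3.09-fold lower, while Ctsd, the gene for cathepsin D, was 1.93-fold higher.

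Of 41 measured secreted factors 15 were higher and 26 lower (camera adjusted p = 0.0445; adjusted p = 0.501 with an estimated correlation). Ccn1, Igfbp6 and Igfbp2 were 3.37-fold, 4.44-fold and 3.09-fold lower, with 0 members passing by either adjustment. This call ended without wild-type replicate 2 (adjusted p = 0.107), 4 (0.129) or 5 (0.104) and without labelled p21-null replicate 2 (0.366), and it ended with normexp correction, no filter, other probe rules, array weights, the replicate block, the series table and both covariates (0.0527 to 0.292). The difference itself was −0.13 without labelled p21-null replicate 2 and −0.49 without replicate 3. Of 38 TGF-β response genes 27 were lower (camera adjusted p = 0.0218; adjusted p = 0.571 with an estimated correlation), among them Ltbp2, at −1.70, and the activin subunit gene Inhba, at −1.68 on the log2 scale; Smad6, an inhibitor of the BMP branch, was 2.04-fold higher. That call ended without wild-type replicate 2 (adjusted p = 0.0692), 4 (0.129) or 5 (0.0587) and without labelled p21-null replicate 3 (0.243), with the replicate block (0.339) and with the liver (0.518) or erythroid (0.957) covariate; the difference was −0.51 without wild-type replicate 3. Lysosomal genes were higher for 31 of 40 members (camera adjusted p = 0.000637; adjusted p = 0.357 with an estimated correlation), Ctsb, the gene for cathepsin B, being 1.92-fold higher; that call ended with the erythroid covariate (difference 0.27, adjusted p = 0.0915). The mean difference of 31 p53 targets was 0.18 (camera adjusted p = 0.265), but 0.0329 without wild-type replicate 3 and 0.29 without wild-type replicate 4, and 0.29 and 0.31 with the liver and erythroid covariates; Gadd45a, Pidd1 and Btg2 were 4.07-fold, 2.49-fold and 2.29-fold higher without passing over the list. FOXO and PI3K genes had a mean difference of 0.0117, a median of −0.17 and a camera direction of down (adjusted p = 0.530); Foxo3 was 2.31-fold higher, Igf1r 1.79-fold and Trib1 2.11-fold lower.

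Markers of neural cells, stroma and gonad were lower in the arrays labelled p21-null, while markers of the mesonephric duct and tubule varied widely within each group. Neural and chromaffin markers differed by −1.36, stroma and smooth muscle markers by −0.70 and gonadal somatic markers by −0.52. S100b, a gene of glia and Schwann cells, was 12.6-fold lower. Gli1, a hedgehog target, was 3.32-fold lower.

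Of 28 neural and chromaffin markers 25 were lower (camera adjusted p = 1.75e-06; adjusted p = 0.357 with an estimated correlation), and 2 members, S100b among them, passed when adjusted over the list alone, against 0 over all genes. Of 27 stroma and smooth muscle markers 22 were lower (camera adjusted p = 0.000171; adjusted p = 0.357 with an estimated correlation), with 0 passing; Nr2f1, a nuclear receptor gene of mesenchyme, was 3.48-fold lower. Of 26 gonadal somatic markers 17 were lower (camera adjusted p = 0.00561; adjusted p = 0.357 with an estimated correlation). Dhh passed when adjusted over that list alone (adjusted p = 0.0111), while Sox9, Cyp26b1 and Irx3, at log2 differences of −2.30, −2.81 and −1.28, did not. Extracellular matrix genes were lower for 33 of 40 members, with a mean difference of −0.51 (camera adjusted p = 0.000171; adjusted p = 0.539 with an estimated correlation); Mfap2, Loxl1 and Fbn2, all of elastic fibres, differed by −1.19, −1.32 and −1.09 on the log2 scale. The matrix difference was −0.30 without wild-type replicate 2, −0.31 without wild-type replicate 5 and −0.76 without wild-type replicate 3, and the stromal one was −0.43 without wild-type replicate 5. For the matrix mean on all arrays the exact permutation test gave p = 0.321. With the erythroid mean as a covariate the neural difference was −0.75 (95% interval −2.78 to 1.28). Within slides 1, 2 and 3 the neural difference was −1.43, −1.48 and −1.66, the stromal one −0.50, −0.16 and −1.82, the gonadal one −0.53, −0.29 and −1.05, and the matrix one −0.0134, −0.58 and −1.32. With slide as a block they were −1.51, −0.78, −0.61 and −0.55.

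The 36 measured duct and tubule markers averaged −0.91 ± 0.85 (SD, n = 5) in wild type and −1.43 ± 0.92 (SD, n = 3) in the arrays labelled p21-null. Their difference of −0.51 was smaller than the spread within either group (exact permutation test, p = 0.500; camera adjusted p = 0.0509; adjusted p = 0.651 with an estimated correlation). The mean was 0.34 in wild-type replicate 1 and −1.90 in wild-type replicate 2, and −1.91 in labelled p21-null replicate 1 and −0.37 in replicate 2. The difference depended on single arrays: it was −0.19 without wild-type replicate 1, −0.25 and −0.22 without labelled p21-null replicates 1 and 3, and −1.06 without labelled p21-null replicate 2. The list was called without wild-type replicate 2 (difference −0.77, adjusted p = 0.00134), 3 (0.0435) or 5 (0.0206) and without labelled p21-null replicate 2 (0.000167). It was also called with slide as a block (−0.59, adjusted p = 0.0396), though within slide 2 its difference was 0.15. The member of smallest p, Bcl2l1, was 2.77-fold higher (limma adjusted p = 0.0673 over the list alone). Hoxb7, a gene of the nephric duct, was 3.97-fold lower, and Ret, its receptor kinase, at least 2.26-fold lower with 4 of 5 wild-type arrays above background. None of these passed. Sim1 was above background on 3 of 5 wild-type arrays and on no array labelled p21-null. Proximal tubule and podocyte markers had a mean difference of 0.25 and a median of −0.15 (camera adjusted p = 0.708). The mean difference was 0.0579 without wild-type replicate 2, 0.0777 without labelled p21-null replicate 1 and 0.47 without labelled p21-null replicate 2. At an unadjusted p under 0.05, 7 members were higher, among them Spp2, Ass1 and Podxl at log2 differences of 2.87, 1.75 and 1.41, and 1 was lower, Wt1 at −1.33. The mean turned negative with the liver (−0.28) or erythroid (−0.32) covariate. Mesothelial markers differed by −0.83 (camera adjusted p = 0.0579; adjusted p = 0.501 with an estimated correlation), and were called with slide as a block (−1.05, adjusted p = 0.0187) and with the liver covariate (−1.44, adjusted p = 0.00212). Without labelled p21-null replicate 2 they differed by −1.30 (adjusted p = 0.00939) and without replicate 3 by −0.48 (adjusted p = 0.381). Endothelial markers differed by 0.0444 (0.877) and germ cell markers by −0.033 (0.877). Without labelled p21-null replicate 2 the endothelial difference was 0.48 (adjusted p = 0.0494), against an adjusted p of 0.958 with an estimated correlation on all arrays.

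Camera with its preset correlation called 17 of the 30 lists, 10 higher and 7 lower in the arrays labelled p21-null. Over the other splits of the same 8 arrays it called a median of 10 lists, so many of these calls need no difference between the groups. With an estimated correlation it called 0, and fry called 0 for movement in 1 direction and 7 for movement in either direction. Of the 17 lists, 15 kept their sign within all 3 slides and 16 were called with slide as a block.

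**Figure D3:**
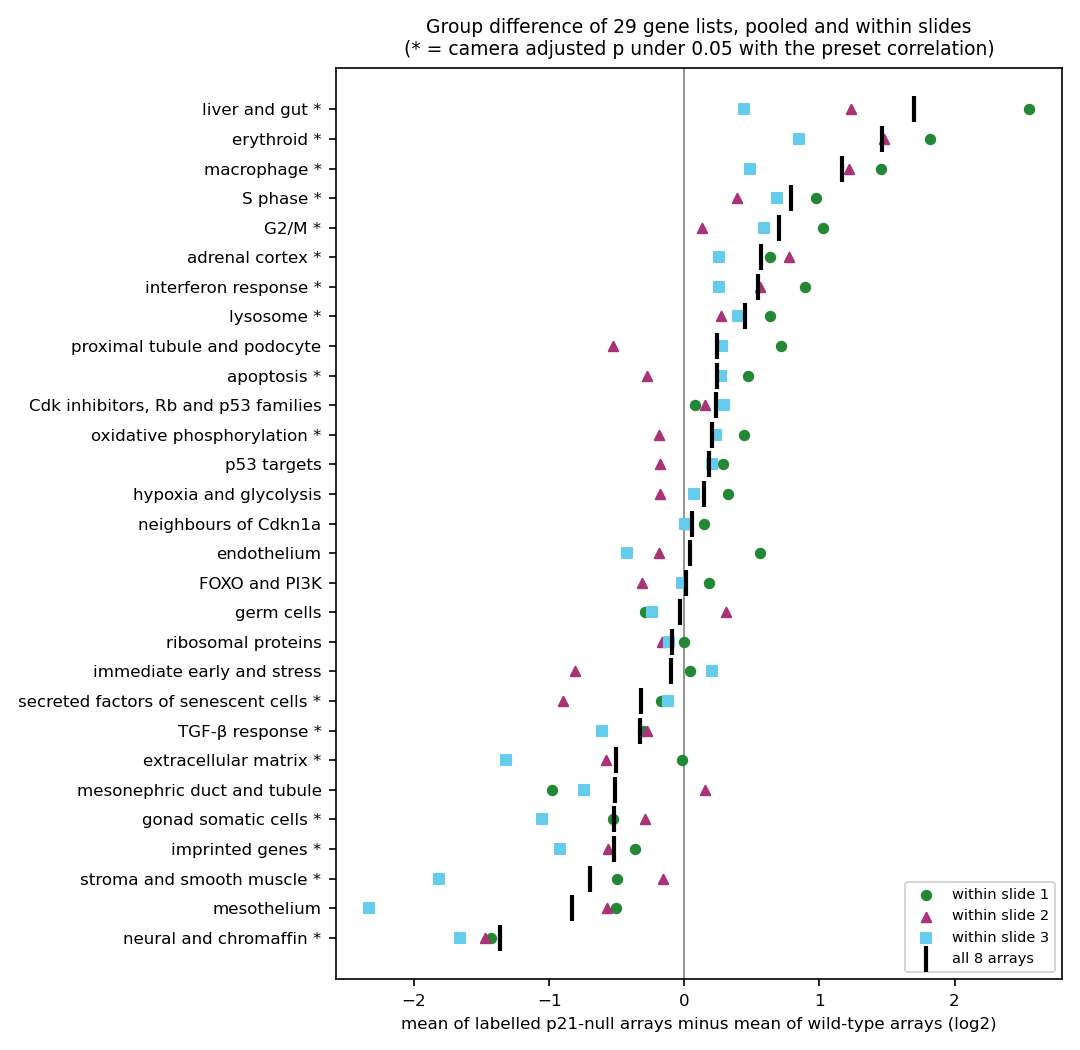
Difference between the mean of the labelled p21-null arrays and the mean of the wild-type arrays (horizontal axis, log2) for 29 gene lists (rows), over all 8 arrays (black bars) and within each of the 3 slides (circles, triangles and squares); an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Liver and gut markers lie highest at 1.70 and neural and chromaffin markers lowest at −1.36.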

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

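Within the 5 wild-type arrays, 145 sets of values (named genes, list means and array quality measures) were searched for 1 array far from the other 4, and 9 were found, where chance alone gives about 1 in 20. The search was set before the data were examined. Wild-type replicate 3 had the lowest mean of the secreted factors of senescent cells (−2.13, the next being −1.49), of the TGF-β response genes (−0.52, the next being 0.32) and of the hypoxia and glycolysis genes (1.02, the next being 1.57). Wild-type replicate 2 had the lowest mean of proximal tubule and podocyte markers (−1.88, the next being −1.08), the lowest signal of the steroid enzyme gene Hsd3b6 (−4.43, the next being −2.39) and the highest of Ltbp2 (0.47, the next being −0.76). The Y-linked genes Ddx3y, Kdm5d and Uty were not well above background on wild-type replicate 5 (−8.29, −8.30 and −7.79), while their lowest values on the other wild-type arrays were −1.70, −1.65 and −2.81.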

How the results depend on the processing

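The liver and erythroid covariates were chosen after the data were seen. All other settings were fixed before, except that normexp correction took median intensities in place of the planned mean ones. In every one of the alternatives the count of genes past the adjusted threshold stayed at 0, except 3 with normexp and the 75th percentile, 8 with array weights, and a range of 0 to 1 on leaving out 1 array. The count of genes at an unadjusted p under 0.01 and at least 2-fold was 2034 with array weights, 131 with the liver and 102 with the erythroid covariate, and 309 to 1306 on leaving out 1 array. Lists called numbered 11 and 9 with these covariates, 0 with an estimated correlation, 0 with fry in 1 direction and 7 in either, and 14 to 18 on leaving out 1 array. Cdkn1a differed by 0.40 and 0.17 with the covariates and by −0.50 to 0.0758 without 1 array. The macrophage difference was 1.18 with slide as a random block, where a model p = 0.0166 stands beside p = 0.0536 by exact permutation test without it. It ranged from 0.97 to 1.41 without 1 array. Its values with the replicate block, array weights or other moderation are not given here.

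With the liver and erythroid covariates, in that order, signs turned for proximal tubule (−0.28, −0.32), endothelial (−0.26, −0.29), stress (0.00113, 0.0476), sex-linked (0.58, 0.94) and Cdkn1a-neighbour genes (−0.10, −0.20), Cdkn1b (−0.25, −0.0808), Ddx3y (3.79, 4.86), Kdm5d (3.35, 4.05) and Uty (2.55, 3.19), for Cdkn1c with the liver one (0.00313), and for interferon (−0.14), liver and gut (−0.30) and oxidative phosphorylation genes (−0.0107) and Spp2 (−0.0715) with the erythroid one. FOXO and PI3K genes turned with normexp and the 75th percentile (−0.0776) or quantiles (−0.0838), the strict filter (−0.16), slide as a block (−0.0167), every probe tested (−0.0494) and the series table (−0.0475). Germ cell markers turned with median scaling (0.0283), no filter (0.0370) and the replicate block (0.0284), stress genes with that block (0.0429), Cdkn1b with quantiles (−0.0327), normexp and quantiles (−0.00545) and the series table (−0.00107), and Cdkn2a (0.37), Ddx3y (0.83), Kdm5d (0.48) and Uty (0.62) with array weights. Kdm5d and Uty also turned with normexp and the 75th percentile (0.00738, 0.0287), normexp and quantiles (0.0297, 0.0656) and the series table (0.0295, 0.0645). Without 1 array, ranges spanning 0 were −0.0549 to 0.0783 for FOXO and PI3K, −0.24 to 0.48 for endothelial, −0.17 to 0.13 for germ cell, −0.24 to 0.0486 for stress and −1.37 to 0.30 for sex-linked genes, −0.12 to 0.25 for Cdkn1b, −1.08 to 0.91 for Cdkn2a, −4.49 to 1.14 for Xist, −2.15 to 2.09 for Ddx3y, −2.16 to 2.03 for Kdm5d, −1.91 to 1.69 for Uty and −0.18 to 1.004 for Eif2s3y. The cause was not tested.

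Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at 0.0675, −0.0856 and −0.0734. Across the groups, arrays of the same slide correlated at 0.0675, 0.0199 and 0.0819 on slide 1, 0.140 on slide 2 and 0.228 on slide 3. Arrays of different slides correlated between −0.121 and 0.0919. The main comparison and the exact permutation tests of 56 splits took no account of slides. With the replicate block 0 genes passed the adjusted threshold, 942 passed the looser count and 13 lists were called. Lists were not tested with slide as a random block. Probes near background limit the folds given as bounds.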

Other observations

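Interferon and antigen-presentation genes were higher in the arrays labelled p21-null by a mean of 0.54, with 26 of 34 members higher (camera adjusted p = 0.000171; adjusted p = 0.358 with an estimated correlation). H2-D1 and H2-K1, the classical class I genes of this list, were 2.76-fold and 2.41-fold higher and passed when adjusted over the list alone, against 0 over all genes. Psmb8, a subunit of the immunoproteasome, was 5.51-fold and Xaf1 2.03-fold higher, neither passing. H2-D1, H2-K1 and Psmb8 lie on chromosome 17, as Cdkn1a does, while Xaf1 lies on chromosome 11. H2-Q7 and Tap2, given above, also lie on chromosome 17. Whether DNA of another strain carried along with the targeted allele reaches these genes was not tested. The list difference was 0.82 without labelled p21-null replicate 2. The call ended without labelled p21-null replicate 1 (difference 0.35, adjusted p = 0.0535) and with the liver mean (difference 0.14, adjusted p = 0.172) or the erythroid mean (−0.14, adjusted p = 0.746) as a covariate. Steroidogenic genes of the adrenal cortex were higher by 0.57 (camera adjusted p = 0.0169; adjusted p = 0.357 with an estimated correlation), with Akr1b7 2.70-fold and Hsd3b6 3.39-fold higher; this call ended without wild-type replicate 4 (adjusted p = 0.0777), with the replicate block (0.132) and with the liver (difference 0.29, adjusted p = 0.178) or erythroid (0.11, adjusted p = 0.571) covariate. Oxidative phosphorylation genes were higher by 0.21 (camera adjusted p = 0.0169; adjusted p = 0.618 with an estimated correlation), and that call ended without wild-type replicate 2 (adjusted p = 0.107) or labelled p21-null replicate 1 (difference 0.13, adjusted p = 0.470), and with the liver (0.824) or erythroid (0.930) covariate; the difference was 0.33 without labelled p21-null replicate 2.

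Imprinted genes were lower for 20 of 24 members, by a mean of −0.52 (camera adjusted p = 0.0218; adjusted p = 0.596 with an estimated correlation), with Nnat at −2.12 and Ndn at −0.97 on the log2 scale. The call ended without wild-type replicate 2 (difference −0.34, adjusted p = 0.234) or 5 (0.157) and without labelled p21-null replicate 2 (0.175), with the replicate block (0.181) and with the liver (difference −0.33, adjusted p = 0.284) or erythroid (−0.26, adjusted p = 0.454) covariate. For the imprinted mean on all arrays the exact permutation test gave p = 0.232. Apoptosis genes had a mean difference of 0.24 (camera adjusted p = 0.0477; adjusted p = 0.571 with an estimated correlation); Bcl2l1, which opposes cell death and is abundant in red cell precursors, was 2.77-fold higher and Bcl2 1.56-fold lower. That call ended without wild-type replicate 2 (adjusted p = 0.167), 3 (difference 0.15, adjusted p = 0.116) or 5 (0.151) and without labelled p21-null replicate 1 (0.411), with slide as a block (0.0712), with the liver (0.280) or erythroid (0.259) covariate, and under most scalings and filters. For the apoptosis mean on all arrays the exact permutation test gave p = 0.286. Hypoxia and glycolysis genes differed by 0.15 (camera adjusted p = 0.308), and by 0.0181 without wild-type replicate 3. Ribosomal protein genes differed by −0.0918 (camera adjusted p = 0.265; adjusted p = 0.859 with an estimated correlation), and were called lower without labelled p21-null replicate 1 (−0.13, adjusted p = 0.0479) and with the liver (−0.30, adjusted p = 0.000849) or erythroid covariate (−0.46, adjusted p = 2.09e-05). Immediate early and stress genes differed by a mean of −0.0959 with a median of 0.0520 (0.716). Slc2a1, the glucose transporter of red cells and other tissues, was 2.51-fold higher and Jun 2.80-fold lower.

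Xist, expressed from the inactive X, and the Y-linked genes Ddx3y, Kdm5d and Uty split the arrays across the groups. On wild-type replicate 5 and labelled p21-null replicate 1, Xist stood at 3.30 and 3.45 and the 3 Y-linked genes were not well above background. On wild-type replicate 2 and labelled p21-null replicates 2 and 3, Xist stood at −5.09, −0.72 and −7.80 with Ddx3y at −0.0040, −0.21 and 0.10. On wild-type replicates 1, 3 and 4 it stood at 2.70, 1.31 and −1.11 with Ddx3y at −1.70, −0.88 and 0.17. On this probe labelled p21-null replicate 2 thus had more Xist than wild-type replicate 4. A second Xist probe was well above background on wild-type replicates 1, 3 and 4 (0.14, −1.78 and −5.12) and not on labelled p21-null replicate 2 (−7.76), so the probes differ on that array. The probes of Eif2s3y and Usp9y were above background on all 8 arrays, those without other Y-linked signal included. As a list the sex-linked genes had a mean difference of −0.62 (camera adjusted p = 0.570).

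The liver and erythroid covariates were chosen after the list differences were seen, though the reading of the S-phase and G2/M values was written down before these were computed. Slide as a block was set before the data were examined, but how its values would be read was written down only after they were seen. The covariate tests of the macrophage list and the test of the neighbours of Cdkn1a were chosen only after the result was seen. The S-phase, G2/M and macrophage lists were higher in the arrays labelled p21-null, by 0.79, 0.70 and 1.17, and liver and blood RNA carried along in the dissection or a difference between slides may account for this. With slide as a block the S-phase difference was 0.73 (95% interval 0.20 to 1.25) and the macrophage difference 1.11 (0.0601 to 2.16), which argues against slides as the whole cause, while that of G2/M was 0.65 with an interval reaching 0 (−0.0561 to 1.35). With the liver mean as a covariate the 3 differences were 0.57 (−0.13 to 1.27), 0.44 (−0.39 to 1.27) and 0.96 (−0.72 to 2.63), so liver tissue stays open for all 3, the intervals holding both 0 and the full difference. With the erythroid mean they were 0.47 (−0.30 to 1.24), 0.33 (−0.59 to 1.26) and 0.70 (−1.13 to 2.54). The G2/M value met the reading written down beforehand for blood cells as the cause, and the S-phase value met neither reading. The erythroid mean itself separates the groups without overlap, so such shrinkage does not tell blood cells from a group effect. That argument was not part of the reading, and blood cells stay open for all 3. The loss of p21, which the design names, stays open as untested beside these.

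Among abundant liver and blood genes, chosen after their values were seen, Alb differed by 1.45, Afp by 0.81, Ttr by 2.10, Apoa2 by 2.28 and Trf by 1.70. The globin genes Hba-a1 and Hbb-bt differed by 0.17 and −0.04, while the embryonic globin gene Hbb-bh1 differed by 2.39. Alb lay at the 86.8 percentile of tested genes on wild-type replicate 2 and between 95.4 and 98.9 on the other 7 arrays. The liver list holds 19 measured genes, several of which (Vil1, Fabp1, Fabp2) other epithelia also express.

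Among 32 measured neighbours of Cdkn1a, Glo1 and Brpf3 were 2.41-fold and 3.54-fold higher and passed when adjusted over the list alone, and Fgd2 and Pim1 were 2.74-fold and 3.37-fold higher without passing. The list had a mean difference of 0.0556 and a median of −0.17 (camera adjusted p = 0.932), and fry found movement in either direction (adjusted p = 0.00260). DNA of another strain carried along with the targeted allele could give such a pattern. Of the 100 tested genes nearest to Cdkn1a 5% had an unadjusted p under 0.01, which lay at the 64.1 percentile of 170 other runs of 100 genes (median 4%), neither above the 95% set for that explanation nor below the median. Carried-along DNA stays open, as does an effect of p21 loss. Blood cells in the material stay open too. Among wild-type arrays Pim1 and Brpf3 were lowest on replicate 2 (−0.77 and −1.08) and highest on replicate 5 (1.14 and 0.66). The erythroid mean was also lowest and highest there (1.57 and 3.44). Glo1 was instead lowest on replicate 5 (2.45) and Fgd2 on replicate 4 (−3.99). With the erythroid mean as a covariate the list difference was −0.20 (95% interval −0.39 to −0.01).

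Other splits of the 8 arrays into 5 and 3 were counted, 56 in all. For genes past the adjusted threshold the real count was 0, so all 56 splits gave as many, and the highest other count was 25. That split set wild-type replicates 1, 3 and 4 apart from the rest. The next highest count, 15, set wild-type replicates 1 and 3 and labelled p21-null replicate 1 apart, all of slide 1. Both splits were picked for their counts out of 56, so these counts alone cannot show a structure among the samples that the groups do not describe. Wild-type replicates 1, 3 and 4, and not labelled p21-null replicate 1, are also the ones with both Xist probes and Ddx3y well above background. Material of several embryos on 1 array could give both signals and was not tested; n = 5 and its SD would then not count single embryos. At an unadjusted p under 0.01 and at least a 2-fold change, 4 of 56 splits gave as many genes as the real 992, the highest other being 1103, so chance cannot be excluded for that count. For lists called by camera 2 of 56 splits gave as many as the real 17, the highest other being 19, a share under 0.05. The median of the other splits was 10 lists, and splits that keep the slides allow no p under 0.0625, so the number of lists called says little about the groups.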
